A study of Homo sapiens with 4 samples.

How the data were processed

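RNA from CWR22Rv1 prostate cancer cells was measured on 4 Illumina expression bead arrays, 2 from cells that carried the pLKO.1 control vector and 2 from cells that carried a Siah2 shRNA. Per the labels' protocols, the cells were selected with puromycin, total RNA was extracted with a column kit, and biotinylated cRNA was prepared with an Ambion kit. The labels number the replicates but do not say whether they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The array software and the normalization behind the authors' value table are not given in the sources used here.

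The authors deposited 2 tables. The first holds, for 47228 probes, each probe's intensity on a linear scale, with no normalization named in the file, and a deposited detection p-value for each array. The second is the authors' value table of 24733 probes, which on comparison were those with a detection p under 0.05 on at least 1 array. Its deposited values are on a log2 scale, since against the log2 of the intensity of bright probes each column had a slope between 1.01 and 1.02. Its column medians were 7.60 and 7.61 for the pLKO.1 arrays and 7.59 and 7.62 for the shSiah2 arrays, and how it was scaled between arrays stays unknown. This table served as an alternative source of values.

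The intensities were processed with limma 3.58.1 in R 4.3.3. The neqc function corrected the background by normexp, with the background taken from the detection p-values, added an offset of 16, applied quantile normalization and took log2. A probe was tested if its detection p was under 0.05 on at least 2 of the 4 arrays, which left 20750 probes. The groups were compared with lmFit and eBayes, two-sided, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the tested probes at a threshold of 0.05. Fold changes are shSiah2 minus pLKO.1 on the log2 scale, given with their standard error (SE). The verbs rose and fell are used for results past that threshold. Where a probe was detected on no array of a group, its change is also given as a bound ("at least N-fold"), the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the probe's own value and the lowest value among detected probes.

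Gene names came from the platform annotation of the probes in the value table, updated through Entrez IDs to the symbols of a RefSeq gene table (assembly GRCh38.p14), which was used for names and gene classes only. One symbol was found for 18007 probes, 17994 of them through the Entrez ID and 13 with the platform's own symbol. A further 4 probes had several symbols and 29217 were unnamed here. The tested probes covered 11894 named genes. A gene in a list was represented by its tested probe with the highest mean. Of 3182 genes with more than 1 tested probe, none had probes called in both directions, and 39 had a called probe beside another of the opposite sign. Probes cannot separate near-identical genes, so the SNORD3, RNU1, HBA, UGT2B and AKR1C genes are uncertain as single genes. The probes of KLK3, KLK2 and NCOR1 carried no name here, and these genes were not analysed here.

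Before the data were examined, 25 gene lists, the test, the alternatives and the rule for named genes were fixed. The rule named SIAH2, the 12 genes with the highest and the 12 with the lowest fold change among called probes whose shSiah2 arrays both lay on 1 side of both pLKO.1 arrays, up to 4 members per list with the largest absolute change, and KLK3, KLK2, TMPRSS2 and FKBP5, besides further genes that are not reported here. Called list members that this rule did not select are also named. They were chosen after their values were seen, and their single values were not followed through the alternatives. The lists held androgen-induced genes, androgen-repressed genes and coregulators of the androgen response; cholesterol and fatty acid genes; motility, epithelial and neuroendocrine genes; DNA replication, mitosis, p53, hypoxia, RAS/MAPK feedback, interferon, NF-kB, unfolded protein response, NRF2, heat shock and proteasome, oxidative phosphorylation, ribosome biogenesis and ribosomal protein genes; SIAH2 partners; and markers of basal, stromal, and leukocyte or endothelial cells. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 25 lists. A list needed at least 3 tested members, a limit set after the lists were first seen, and the smallest had 4. An estimated correlation, fry and the mean of a gene's probes were alternatives. With an estimated correlation, camera also takes its degrees of freedom from the few arrays and not from the genes. Members at a bound changed the median of 1 list by over 0.005, that of leukocyte and endothelial markers.

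Other alternatives were no background correction, normexp with offset 50, cyclic loess, scaling to the 75th percentile, the authors' value table, no filter or a stricter filter on dim probes, an intensity trend with robust variances, the replicate number as a block, each array left out, other thresholds, and 1 probe per gene. The method was tested on simulated data made to resemble this comparison, 5 runs with 200 changed probes each and a median of 20462 tested probes. It called 46.0% of 4-fold changes and 0.2% of 2-fold changes in the right direction, and 1.70% of its calls were unchanged probes. A list of 25 genes shifted by 0.6 was called in 5 of 5 runs, and 0 of 100 unshifted lists were called. In these list runs the probes varied independently and no other gene changed, so false calls of lists with correlated members were not tested. These rates hold for the simulated runs only, since the cutoff that Benjamini-Hochberg sets depends on how many probes change. Figures were drawn with matplotlib 3.10.9.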

Results

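Expression was measured in CWR22Rv1 cells, a human prostate carcinoma line derived from a xenograft that relapsed after castration. The 2 control arrays carried RNA from cells with the empty pLKO.1 vector, and the 2 knockdown arrays carried RNA from cells with an shRNA against Siah2, an E3 ubiquitin ligase. Between 19862 and 20632 probes were detected per array, 42.1% to 43.7% of all probes, and the mean signal lay between 650 and 846. Across the tested probes, the arrays of a group correlated at 0.985 (pLKO.1) and 0.983 (shSiah2), and arrays of different groups at 0.957 to 0.969. The number of arrays limits the precision. The series title poses the question of whether Siah2 regulates androgen-driven transcription in castration-resistant prostate cancer.

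SIAH2 itself fell in the knockdown cells, by 1.85 on the log2 scale (SE 0.251, adjusted p = 0.00117 by limma, probe ILMN_1801313). Its normalized intensity was 8.21 ± 0.179 (SD, n = 2) on the pLKO.1 arrays and 6.36 ± 0.219 (SD, n = 2) on the shSiah2 arrays. The deposited signals were 334.5 and 490.5 against 185.2 and 196.8, and the probe was detected on all 4 arrays. The size of the fall depends on the background correction, and without it the value was -1.03. KLF10 was the only one of the 14 tested genes of the SIAH family and known SIAH2 partners to pass the threshold, and it rose by 1.81 (adjusted p = 0.00183). The partner list as a whole had a median of 0.14 and did not pass (camera adjusted p = 0.134), with 1 member past the threshold adjusted over the list alone. Its median was 0.27 without pLKO.1 replicate 1, 0.07 with 75th percentile scaling and 0.06 with the authors' value table. DYRK2 at 0.89, TNK2 at -0.61 and SPRY2 at 0.48 did not pass.

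In all, 1284 probes passed the threshold, 6.19% of those tested, with 512 higher and 772 lower in shSiah2 cells. These named 374 genes that rose and 599 that fell, while 197 called probes were unnamed here. Changes of at least 4-fold were seen for 47 higher and 107 lower probes. The count was 640 with no filter on dim probes, 520 without pLKO.1 replicate 1 and 800 without shSiah2 replicate 2.

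**Figure D1:**
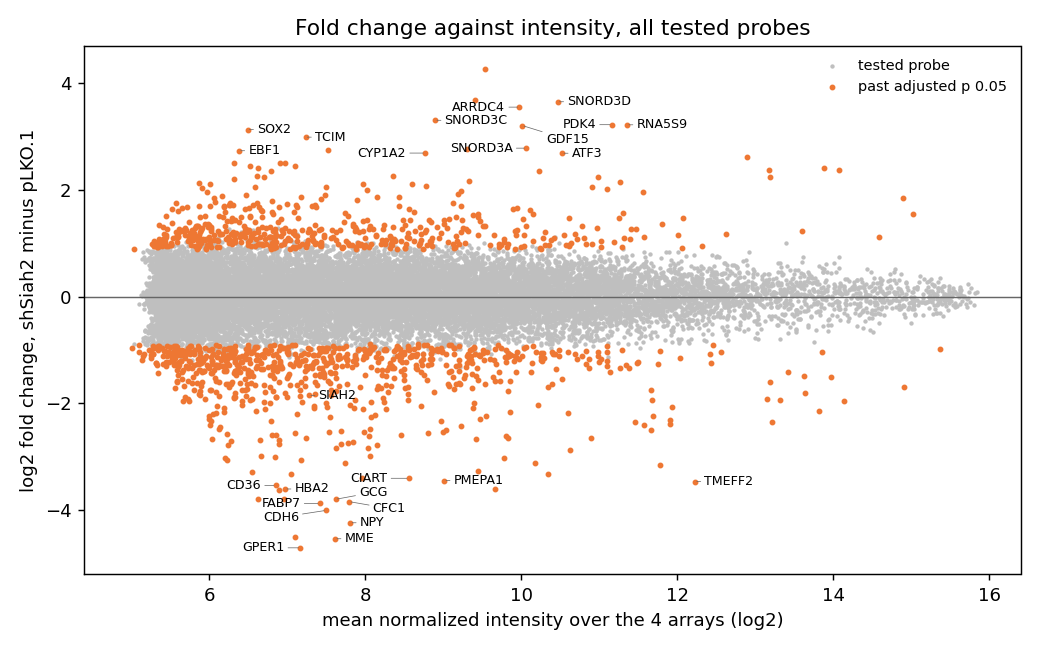
Log2 fold change (shSiah2 minus pLKO.1) of each of the 20750 tested probes against its mean normalized log2 intensity over the 4 arrays, with the 1284 probes past the threshold in orange. SIAH2 and the 12 highest and 12 lowest named genes are labelled, and unlabelled probes farther out carry no gene name here or belong to a gene already shown by another probe or not selected by the naming rule.

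Among the 12 named genes with the largest falls, GPER1, a G protein-coupled receptor that responds to estrogen, fell by 4.71 (at least 16.7-fold), and MME, the cell-surface peptidase neprilysin, fell by 4.53 (at least 21.4-fold). The neuropeptide gene NPY fell by 4.24, and the cadherin gene CDH6 fell from 9.50 ± 0.173 to 5.50 ± 0.189 (SD, n = 2 per group). The fatty acid-binding protein gene FABP7, CFC1 and the glucagon gene GCG fell too, at -3.87, -3.84 and -3.80. TMEFF2, a transmembrane protein gene expressed in prostate, fell by 3.46, from 13.96 ± 0.0702 to 10.50 ± 0.0728 (SD, n = 2 per group). CIART, a circadian repressor gene, fell by 3.40. The SE of these 9 genes lay between 0.237 and 0.296. Among the 12 largest rises, ARRDC4, an arrestin-domain gene, rose by 3.55 (SE 0.302), PDK4, a kinase that inhibits pyruvate dehydrogenase, by 3.22 (SE 0.277), GDF15, a stress-induced cytokine, by 3.21 (SE 0.268) and the transcription factor gene ATF3 by 2.69 (SE 0.237). SOX2 rose by 3.13 (at least 6.09-fold), TCIM by 2.99, EBF1 by 2.74 (at least 4.91-fold) and CYP1A2, a xenobiotic-metabolizing enzyme gene, by 2.69. Small non-coding RNA genes also ranked among the highest, with SNORD3D at 3.65, SNORD3C at 3.31, the 5S rRNA gene RNA5S9 at 3.22 and SNORD3A at 2.78.

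Androgen-induced genes were lower as a list. Of 29 tested members, 7 fell, 0 rose and 22 did not pass, and 9 fell adjusted over the list alone. PMEPA1, an androgen-induced inhibitor of TGF-beta signalling, fell by 3.45 (SE 0.266, adjusted p = 2.34e-05). AZGP1, the prostate-specific transporter gene SLC45A3 (prostein) and the lipid phosphatase gene PLPP1 fell as well, at -3.33, -3.31 and -2.87. ACP3, which encodes prostatic acid phosphatase, fell by 1.62 (at least 2.28-fold), NDRG1 by 1.40 and the serine protease gene TMPRSS2 by 1.14. FKBP5, another androgen-induced gene, did not pass at -0.22 (SE 0.252, adjusted p = 0.678). The list median was -0.12 and the mean -0.60 (camera adjusted p = 0.00852, and adjusted p = 0.355 with an estimated correlation). The median was -0.30 to -0.24 when each array was left out in turn, the lowest without pLKO.1 replicate 1, and the highest without shSiah2 replicate 2. It was -0.23 with 75th percentile scaling, -0.22 with the authors' value table and -0.25 with the mean of a gene's probes. NDRG1 did not pass without pLKO.1 replicate 1, at -1.34, nor did TMPRSS2 without that array, at -1.05, or without shSiah2 replicate 2, at -1.02.

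Androgen-repressed genes were lower as a list, with a call lost under several alternatives. Of 10 tested, 4 fell and 0 rose, with 4 that fell and 1 that rose adjusted over the list alone. The 4 were DDC at -2.98, the androgen-glucuronidating enzyme genes UGT2B15 at -1.62 and UGT2B17 at -1.56, and PRUNE2 at -1.41. The list median was -0.23 (camera adjusted p = 0.0455, and adjusted p = 0.392 with an estimated correlation), and the call was lost without background correction (median -0.12), with the stricter detection filter (median -0.05), by fry and with the mean of a gene's probes, while normexp at offset 50 gave a median of -0.15. It was also lost without pLKO.1 replicate 2 (median -0.24), and the median was -0.71 without shSiah2 replicate 1 and -0.36 without pLKO.1 replicate 1. PRUNE2 did not pass without pLKO.1 replicate 2, at -1.04, or without shSiah2 replicate 2, at -1.17. The 20 coregulators and pathway members of the androgen response had a median of 0.14 and did not pass (camera adjusted p = 0.548), with 3 that rose and 2 that fell adjusted over the list alone. Their median was 0.09 with 75th percentile scaling and with the authors' value table, and camera's direction turned with the stricter detection filter (median 0.10). Of the members, the prostate transcription factor genes HOXB13 and GATA2 fell by 1.58 and 1.46, while the glucocorticoid receptor gene NR3C1 rose by 1.39 and MDM2 by 1.09. GATA2 did not pass without pLKO.1 replicate 1, at -1.22. NR3C1 did not pass without pLKO.1 replicate 2, at 1.28, or without shSiah2 replicate 2, at 1.10.

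**Figure D2:**
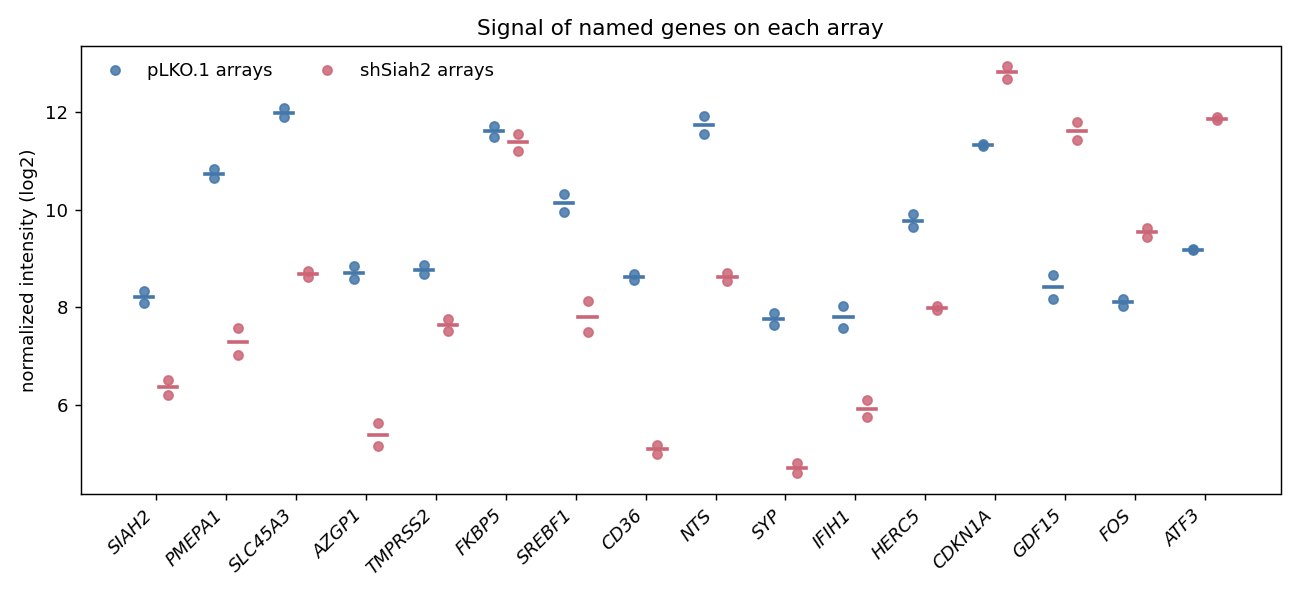
Normalized log2 intensity of 16 named genes on each array, with 1 point per array and a bar at the mean of the 2 arrays of a group. SIAH2, PMEPA1, SLC45A3 and AZGP1 lie lower on both shSiah2 arrays than on both pLKO.1 arrays, GDF15 and ATF3 lie higher, and the FKBP5 means are 11.61 and 11.38.

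Lipid genes were lower. Of 25 genes of fatty acid and triglyceride metabolism, 5 fell and 0 rose, and the list median was -0.44 (camera adjusted p = 0.00564, and adjusted p = 0.355 with an estimated correlation). Adjusted over the list alone, 6 fell and 1 rose. The fatty acid transporter gene CD36 fell by 3.54 (at least 8.93-fold), and SREBF1, a transcription factor gene of lipid synthesis, lay at -2.34. The other 3 were the lipid droplet gene PLIN2 at -1.29, the elongase gene ELOVL6 at -1.12 and the desaturase gene SCD at -1.03. Of 19 genes of cholesterol synthesis and sterol response, 2 fell, LSS by 1.08 and NSDHL by 0.98, and 7 fell adjusted over the list alone. INSIG1 at -0.89 and EBP at -0.77 did not pass over all probes. The cholesterol list had a median of -0.29 (camera adjusted p = 0.00895, and adjusted p = 0.392 with an estimated correlation), a call lost by fry and without pLKO.1 replicate 1 (median -0.25), and the median was -0.48 without pLKO.1 replicate 2. Without pLKO.1 replicate 1, PLIN2 at -1.21, ELOVL6 at -1.11, LSS at -0.96 and NSDHL at -0.99 did not pass. ELOVL6 and NSDHL also missed it without pLKO.1 replicate 2, at -1.13 and -0.97, LSS without shSiah2 replicate 1, at -1.02, and NSDHL without shSiah2 replicate 2, at -0.71. SCD was not followed singly in these fits.

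Neuroendocrine markers moved in both directions. Of 10 tested, 4 fell and 2 rose, and 5 fell adjusted over the list alone. The secretogranin gene SCG3 fell by 3.29 (at least 6.67-fold), the neurotensin gene NTS lay at -3.11, the synaptic vesicle gene SYP at -3.05 (at least 4.90-fold) and DDC at -2.98, while SOX2 and the synaptic gene SNAP25, at 1.66, rose. The list median was -0.58 (camera adjusted p = 0.0103, and adjusted p = 0.373 with an estimated correlation).

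The p53 target list and the RAS/MAPK feedback list were higher. Of 23 p53 targets, 5 rose and 0 fell, and 7 rose adjusted over the list alone. Besides GDF15, the cell cycle inhibitor gene CDKN1A rose by 1.48 (SE 0.243, adjusted p = 0.00397), PHLDA3 by 1.46, the stress-response gene SESN2 by 1.11 and the p53 ligase gene MDM2 by 1.09. The list median was 0.50 (camera adjusted p = 6.80e-06, and adjusted p = 0.355 with an estimated correlation). SESN2 did not pass without pLKO.1 replicate 1, at 0.99, or without shSiah2 replicate 2, at 1.12, and MDM2 was lost without pLKO.1 replicate 1, at 0.77, without shSiah2 replicate 1, at 1.08, and without shSiah2 replicate 2, at 1.10. Of 20 RAS/MAPK feedback genes, 5 rose and 0 fell, and 8 rose adjusted over the list alone. The 5 called over all probes were the MAPK phosphatase gene DUSP4 at 1.66 (at least 2.04-fold), the immediate-early genes FOS at 1.43 and EGR1 at 0.92, SPRED1 at 1.07 and ETV4 at 1.06. The median was 0.58 (camera adjusted p = 3.86e-05, and adjusted p = 0.355 with an estimated correlation), and 0.37 without background correction. SPRED1 and ETV4 did not pass without pLKO.1 replicate 1 (1.09 each), without pLKO.1 replicate 2 (1.05 and 1.04) or without shSiah2 replicate 2 (0.80 and 1.01). EGR1 was not followed singly in these fits.

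Interferon-stimulated genes were lower. Of 32 tested, 6 fell and 0 rose, and 10 fell adjusted over the list alone. The RNA sensor gene IFIH1 fell by 1.89, HERC5 by 1.79, PARP14 by 1.44, PARP9 by 1.33, MX1 by 1.27 and IFITM1 by 1.26 (at least 1.65-fold). The median was -0.20 (camera adjusted p = 0.00564, and adjusted p = 0.355 with an estimated correlation), -0.09 without background correction, -0.12 with normexp at offset 50, -0.32 with the mean of a gene's probes and -0.41 without shSiah2 replicate 2. The call was lost by fry and without shSiah2 replicate 1 (median -0.18). PARP14 did not pass without pLKO.1 replicate 1, at -1.35.

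**Figure D3:**
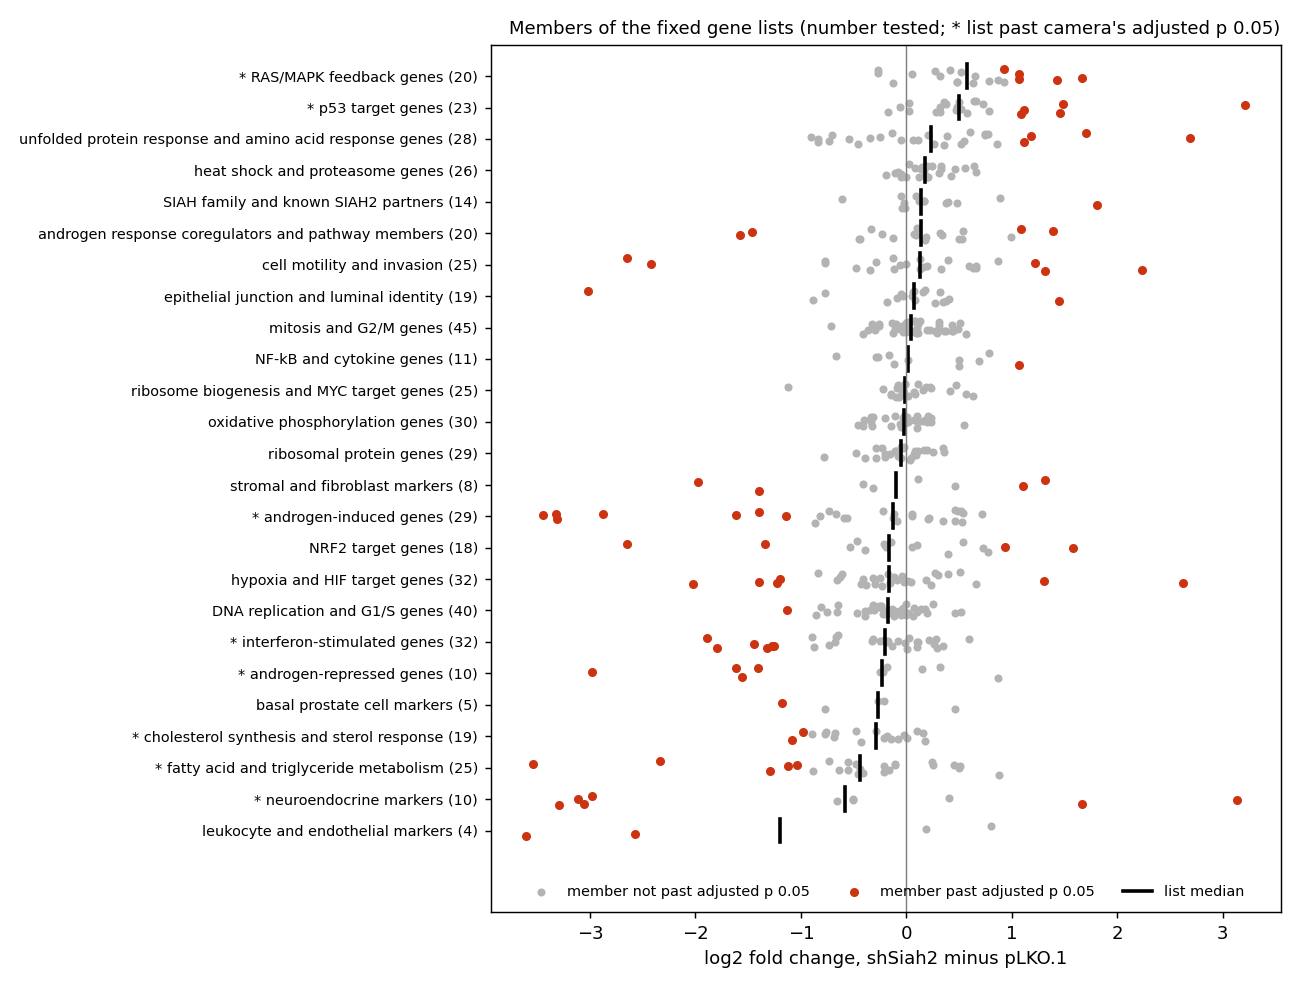
Log2 fold change (shSiah2 minus pLKO.1) of each tested member of the 25 fixed gene lists, 1 point per gene, in red where the gene passed the adjusted threshold, with a black bar at the list median and an asterisk where the list passed camera's adjusted p. The 7 called androgen-induced genes lie between -3.45 and -1.14, whereas the list median is -0.12.

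The other lists did not pass the camera test. Among 32 hypoxia and HIF targets, 2 rose and 4 fell, and the median was -0.17 (adjusted p = 0.232). Single arrays moved this median, to 0.0060 without shSiah2 replicate 2, -0.30 without shSiah2 replicate 1 and -0.26 without pLKO.1 replicate 2, and it was -0.27 with 75th percentile scaling and -0.26 with the authors' value table. The glucose transporter gene SLC2A1 rose by 2.62 and ADM by 1.30, whereas ALDOC, NDRG1, ANKRD37 and PFKFB4 fell by 2.02, 1.40, 1.23 and 1.20. ADM did not pass without pLKO.1 replicate 2, at 1.14, nor NDRG1 without pLKO.1 replicate 1, at -1.34. Adjusted over the list alone, 2 hypoxia genes rose and 5 fell. Among 28 genes of the unfolded protein and amino acid responses, 4 rose and 0 fell, with a median of 0.23 (adjusted p = 0.123, and 0.0427 without shSiah2 replicate 2, where the median was 0.32). Without shSiah2 replicate 1 the median was 0.0065 (adjusted p = 0.405), and with the stricter detection filter 0.09 (adjusted p = 0.645). ATF3, CHAC1 at 1.70 (at least 2.42-fold), SLC3A2 at 1.18 and SESN2 were the 4, and SLC3A2 did not pass without pLKO.1 replicate 1, at 1.26, or without pLKO.1 replicate 2, at 1.11. Adjusted over the list alone, 8 of them rose and 4 fell. Among 18 NRF2 targets, 2 rose and 2 fell (median -0.17, adjusted p = 0.906), and 4 rose and 2 fell adjusted over the list alone. The NRF2 median was -0.05 without shSiah2 replicate 2, -0.08 without shSiah2 replicate 1, -0.10 without pLKO.1 replicate 2, -0.08 without background correction, -0.10 with normexp at offset 50 and -0.09 with the mean of a gene's probes. The steroid-metabolizing reductase genes AKR1C3 and AKR1C2 fell by 2.65 and 1.34, whereas HMOX1 and TXNRD1 rose by 1.58 and 0.93. AKR1C2 did not pass without pLKO.1 replicate 2, at -1.14, and TXNRD1 passed in none of the fits without 1 array, at 0.83 to 1.03.

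Motility genes moved both ways, with 3 that rose and 2 that fell of 25 (median 0.13, adjusted p = 0.529), and 4 each way adjusted over the list alone. The motility median was 0.06 without pLKO.1 replicate 2, 0.25 without shSiah2 replicate 2, 0.23 without pLKO.1 replicate 1, 0.0060 with 75th percentile scaling, 0.0087 with the authors' value table and 0.01 with the mean of a gene's probes. The intermediate filament gene VIM fell by 2.64 and TNS3 by 2.42, while CD44 rose by 1.31 and ROCK1 by 1.22. PLAUR rose by 2.24 on its brighter probe and lay at -0.82 on another. CD44 did not pass without pLKO.1 replicate 1, at 1.10. Of 19 epithelial and luminal genes, the keratin gene KRT19 fell by 3.02 and ELF3 rose by 1.45, with the same counts adjusted over the list alone. RAB25 at -0.89 and CLDN4 at -0.77 did not pass. That list's median was 0.07 and camera's direction was up, whereas its mean was -0.07 and fry's direction was down (camera adjusted p = 0.903). The median was 0.03 without pLKO.1 replicate 1, 0.17 without pLKO.1 replicate 2, 0.13 without shSiah2 replicate 1, 0.04 with cyclic loess and 0.16 with the stricter detection filter.

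Cell cycle and housekeeping lists held few or no calls. Of 40 DNA replication and G1/S genes, E2F2 fell by 1.13, and the median was -0.18 (adjusted p = 0.102, and between 0.0238 and 0.0477 in 5 alternatives). Without shSiah2 replicate 2 this median was -0.09 (adjusted p = 0.312). E2F2 did not pass without pLKO.1 replicate 1, at -0.99, or without shSiah2 replicate 2, at -0.87, and it alone passed adjusted over the list alone. E2F1 at -0.86, MCM2 at -0.81 and POLA2 at -0.76 did not pass. No member of 6 further lists was called by limma over all probes except in the NF-kB list, and none was called adjusted over the list alone apart from 2 NF-kB genes that rose. At an unadjusted p under 0.05 limma passed 2 mitosis, 4 NF-kB, 2 heat shock and proteasome, 0 oxidative phosphorylation, 3 ribosome biogenesis and 1 ribosomal protein genes. Of 45 mitosis genes (median 0.05, adjusted p = 0.550), PLK1 lay at -0.71 and CENPE at 0.57. Of 11 NF-kB and cytokine genes (median 0.01, adjusted p = 0.359), PTGS2 rose by 1.07 and NFKB2 lay at 0.79 on its brighter probe. Another NFKB2 probe rose by 1.00 (adjusted p = 0.0311 by limma). PTGS2 did not pass without either pLKO.1 array, at 1.07 each time, or without shSiah2 replicate 1, at 1.00. Of 26 heat shock and proteasome genes (median 0.17, adjusted p = 0.102, 0.0283 without background correction and 0.0477 with normexp at offset 50, but 0.324 with 75th percentile scaling and 0.22 with the authors' value table, where the median was 0.07 both times), PSMD11 lay at 0.66 and HSPA1A at 0.64. Of 30 oxidative phosphorylation genes (median -0.02, adjusted p = 0.764), ATP5F1C lay at 0.54 and NDUFV1 at -0.46. The 25 ribosome biogenesis and MYC targets had a median of -0.01 but a mean of 0.04 (adjusted p = 0.659), with RRP9 at -1.12. The 29 ribosomal protein genes had a median of -0.05 (adjusted p = 0.762), with RPL14 at -0.78. Medians this close to 0 moved with the processing and with single arrays. Over all alternatives and arrays left out they spanned -0.05 to 0.08 for mitosis, -0.14 to 0.05 for oxidative phosphorylation, -0.18 to -0.0024 for ribosomal protein genes, -0.05 to 0.07 for ribosome biogenesis and 2.54e-04 to 0.50 for NF-kB, the last highest with the stricter detection filter. For mitosis, oxidative phosphorylation and ribosomal protein genes the lowest came with 75th percentile scaling. The heat shock and proteasome median was 0.11 without pLKO.1 replicate 1.

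Few markers of other cell types could be tested. Of the 20 genes of the leukocyte and endothelial list, which also holds globin genes, 4 were tested, and of 17 stromal and 14 basal markers 8 and 5. Of these 4, the leukocyte markers CD14 and CD68 lay at 0.80 and 0.18. The others were the alpha globin genes HBA2 and HBA1, which mark red blood cells and which the probes cannot separate. They fell by 3.60 (at least 9.94-fold) and 2.58 (at least 4.17-fold), and the lower median of the list rests on them. The median was -1.20, or -0.94 with these bounds (adjusted p = 0.0760). It passed by fry (adjusted p = 0.0336), with an intensity trend (0.0474), without pLKO.1 replicate 1 (0.0241) and without shSiah2 replicate 1 (0.0242), but in no other alternative run. The median was -0.47 without background correction (adjusted p = 0.116), -0.66 with normexp at offset 50 (0.0586), -0.73 with the authors' value table (0.0546) and -0.22 with no filter (0.0989). Adjusted over the list alone, 1 member rose and 2 fell. Of 8 stromal markers (median -0.10, adjusted p = 0.764), DCN and FBLN1 fell by 1.98 and 1.40 and LUM and ACTA2 rose by 1.32 and 1.10, the same counts as adjusted over the list alone. The stromal median was -0.46 without shSiah2 replicate 1, -0.23 without pLKO.1 replicate 1, -0.05 without pLKO.1 replicate 2 and 0.25 without shSiah2 replicate 2. It was -0.03 without background correction, -0.05 with normexp at offset 50, -0.06 with 75th percentile scaling and with the authors' value table, 0.11 with no filter and 0.46 with the stricter detection filter. A second DCN probe, detected on no pLKO.1 array, lay at 0.67 (at least 1.21-fold) and did not pass. Without pLKO.1 replicate 1, FBLN1 at -1.20, LUM at 1.25 and ACTA2 at 1.07 did not pass, and ACTA2 also missed it without pLKO.1 replicate 2, at 1.14, and without shSiah2 replicate 1, at 0.94. Of 5 basal markers (median -0.27, adjusted p = 0.224), SFN fell by 1.17 and KRT15 lay at -0.78 (at least 1.23-fold), with 2 that fell adjusted over the list alone. The basal median was -0.80 without shSiah2 replicate 1, -0.45 without shSiah2 replicate 2, -0.14 without pLKO.1 replicate 1, -0.10 without background correction and -0.17 with normexp at offset 50. SFN did not pass without pLKO.1 replicate 1, at -1.12, without pLKO.1 replicate 2, at -1.23, or without shSiah2 replicate 2, at -0.99.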

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

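The smallest-list limit and the small non-coding and ribosomal RNA count, with or without 2 long ribosomal RNAs, were chosen after the data were seen. The SIAH2 knockdown passed the threshold in every alternative run, at -2.004 to -1.03. Of 80 other called genes that the naming rule selected, 54 passed in every alternative that tested them and 0 reversed, while 63 of 1254 values no longer passed. Genes named beyond the rule were not followed singly through the alternatives. The count of 1284 probes became 640 with no filter, where 47228 probes were tested, 2094 at adjusted p 0.10, and 520 to 1329 with each array left out, the lowest without pLKO.1 replicate 1. Leaving an array out puts 1 array against 2, with the lone array assumed to vary like the others. The 1.5-fold limit removed no probe, so it shows nothing. Lower calls made up 55.0% to 66.3%, against 60.1%. With an estimated correlation 0 lists passed, against 8 (1 at an unadjusted p under 0.05), and the androgen-induced list, median -0.12, no longer did. The other list alternatives gave 6 to 10. Of the 8, the cholesterol and p53 lists had estimates over the preset 0.01, at 0.0288 and 0.0575. The others had estimates of -0.0908 to -0.0168, so a higher correlation does not explain the loss of their calls. The fewer degrees of freedom of that option can. They apply to all 8 lists, so the cholesterol and p53 calls were not necessarily lost to correlation. With the replicate number as a block 1815 probes passed. Deviations of the replicate 1 arrays from their group means correlated at 0.0891 across the tested probes. With 2 arrays per group, the replicate 2 arrays mirror them and add nothing. This value does not show that the numbers pair the arrays or that they do not.

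Results not past the threshold reversed in places, and the cause was not tested. For lists the sign is that of the set test, beside the median. Ranges cover all 4 fits that leave out an array, of which only the named ones reversed. Stromal markers reversed without background correction (-0.0334), with the authors' value table (-0.0598), with the mean of a gene's probes (-0.103) and without shSiah2 replicate 2 (range -0.459 to 0.254). The epithelial list did so with 75th percentile scaling (0.0516), by fry (0.0693) and without pLKO.1 replicate 1 or shSiah2 replicate 2 (range 0.0318 to 0.174), coregulators with the stricter filter (0.0954), and NRF2 targets with the mean of a gene's probes (-0.0939) and without pLKO.1 replicate 2 or shSiah2 replicate 2 (range -0.140 to -0.0535). Oxidative phosphorylation genes reversed without pLKO.1 replicate 2 or shSiah2 replicate 1 (range -0.121 to 0.0510), CD68 without shSiah2 replicate 1 (range -0.27 to 0.63) and TRIM29 without shSiah2 replicate 2 (range -0.94 to 0.40). The slide block was not run, as no slide is named in the files used here. Signal over background limits dim probes: 84 called probes were detected on no pLKO.1 array and 157 on no shSiah2 array.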

Other observations

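The genes of this part outside the fixed lists, the small non-coding and ribosomal RNA class, and the tests of background correction held fixed, of a general fall of androgen-induced genes and of p53 targets without ATF4-driven members were chosen only after the results were seen. The single genes of this and the next paragraph were mostly picked because they changed, and no group of them was tested. Those that fell include the secretory granule gene VGF at -2.31, the synaptotagmin gene SYT4 at -2.495, the neuropeptide gene NMB at -3.16 and STMN3 at -3.26. SRRM4, a neuronal splicing regulator gene, fell by 2.78 (at least 4.48-fold) and CELF3 by 2.47 (at least 3.74-fold). STEAP1 at -2.18, DPP4 at -2.09 and KLK11 at -2.73 fell as well. The MHC class II genes HLA-DQB1 and HLA-DMB fell by 2.15 and 1.63, whereas HLA-DRA lay at 0.68 and did not pass.

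Genes that rose include CCN2 at 2.07, CCN1 at 1.39, JUN at 1.33, NR4A2 at 1.86, SIK1 at 2.35, RHOB at 1.54 and EDN1 at 1.23. Of the aryl hydrocarbon receptor targets looked at, CYP1A1 rose by 1.59 beside CYP1A2, whereas CYP1B1 at -0.39 and TIPARP at 0.39 did not pass. TXNIP, a close relative of ARRDC4, lay at 0.54 and did not pass (adjusted p = 0.230). Among 230 long non-coding RNA genes, 1 rose and 12 fell, beside 294 and 510 of 11239 protein-coding genes. The share that fell was thus near that of protein-coding genes and the share that rose was lower, and the class was not tested.

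Small non-coding and ribosomal RNA genes were higher as a class: 26 of 134 tested rose, against 2 that fell (RNY1 and SNORD13), with a median over all 134 of 0.42 (camera p = 1.69e-11, and p = 0.0377 with an estimated correlation). The class holds 2 long ribosomal RNAs, RNA28SN5, which rose by 1.85, and RNA18SN5 at 0.65, which did not pass; without them 25 of 132 rose, with a camera p of 4.79e-11 and p = 0.0399 with an estimated correlation. In the neqc values, all 14 snRNA genes lay above 0 and 8 rose. The 8 include the U1 genes RNU1-1, RNU1-3, RNVU1-18 and RNVU1-7, and the 26 include SNORD3A, SNORD3C and SNORD3D. Probes may not separate such near-identical genes, so 1 signal may enter these counts and camera's p more than once. The count of 26 fell to 17 without background correction, 15 with no filter, 16 with the stricter filter and 16 without pLKO.1 replicate 1. More non-polyadenylated RNA of all lengths in the knockdown labelling would also raise replication-dependent histone mRNAs. The median of 31 such genes was 0.0135 (SE 0.106), so histone mRNAs showed no shared gain. This does not exclude a gain of other long RNAs, since the long RNA28SN5 rose by 1.85. Histone mRNAs of this kind also depend on DNA replication, whose genes had a median of -0.18 in a list that did not pass. A fall from that side could hide a gain. A gain limited to small RNAs would not reach histone mRNAs, so it was not tested and stays open. The prediction written before the result, for scaling between arrays as the cause, was that the median of the 26, 1.28, would fall under 1 in some normalization; it did, at 0.576 (SE 0.286) without background correction, 0.755 with normexp at offset 50 and 0.819 in the authors' value table, but the first 2 of these change the background correction and keep the quantile scaling, and the value table's scaling is unknown, so they do not test scaling. In a test chosen after those values were seen, the background correction was held fixed. The median was then 1.23 (SE 0.112) with no scaling between arrays, 1.27 with cyclic loess and 1.32 with 75th percentile scaling. The 26 were picked by their neqc values, so these medians show only that their rise was there before the scaling step. The part that the background correction plays stays open.

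The list of androgen-induced genes had a mean of -0.60 and a median of -0.12, with 7 of 29 members called, and its camera call (adjusted p = 0.00852) was lost with an estimated correlation (adjusted p = 0.355). That estimate was -0.0323, under the preset 0.01, so a higher correlation does not explain the loss. The expression level of the members is argued against, since the mean lay at percentile 0 among 10000 random lists matched on expression, whose 95% range was -0.23 to 0.19. The low mean rests largely on the 7 called members, which lay between -3.45 and -1.14, while 12 of the 29 members lay above 0. The share under 0, 58.6%, met the limit written as counting against a general fall. Its exact binomial interval of 38.9% to 76.5% is wide, however. A smaller fall across the list therefore cannot be told apart from falls of a few members. A fall limited to a subset of these genes remains a hypothesis. The androgen-repressed list did not move the opposite way. Of its 10 tested members 4 fell and 0 rose, with a median of -0.23 (camera adjusted p = 0.0455), a call lost under several alternatives. An effect of the knockdown, an off-target effect of the shRNA and a difference between the selected cell populations stay open, since the labels name 1 shRNA and 1 control.

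The p53 target list had a median of 0.50, and its camera call (adjusted p = 6.80e-06) was lost with an estimated correlation (adjusted p = 0.355). That estimate was 0.0575, over the preset 0.01, but the option also has fewer degrees of freedom. The stress factor ATF4 also drives GDF15, SESN2 and other members, and without them the median of the remaining 17 genes was 0.481 (SE 0.111), which argues against those members as the whole cause. Camera's p for these 17 was 2.95e-05, and p = 0.0801 with an estimated correlation. The expression level of the members is argued against as well, with the list's mean at percentile 100 among 10000 matched random lists. A p53 response may be 1 explanation, as a hypothesis, and the selection and off-target differences above stay open and were not tested.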
